A study of Mus musculus with 2 samples.

How the data were processed

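Scl chromatin immunoprecipitation DNA of the HPC-7 line was sequenced on Illumina Genome Analyzers in 3 portions. Per the labels, cells were fixed in formaldehyde at 0.4% and chromatin was sheared to between 200 and 500 bp. Sample 1 joins the portions of lanes 7 and 8, and sample 2 is the portion read at the other site. Only 1 group exists, so no comparison between groups was made.

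Per the labels, sample 1 was aligned with the Solexa alignment software and sample 2 with Eland, and the text deposited with the files gives build mm9 for sample 1 and mm8 for sample 2. Versions are not given in the sources used here. The deposited sample 1 file gives a start, an end, a strand and a score per read, the score running from 43 to 45 for reads of 45 bp, and 45 minus the score was taken as the number of mismatches. Whether that file holds only uniquely placed reads is not stated. The deposited sample 2 file of unique reads gives the sequence, the position and, per read, the count of genome matches with 0, 1 and 2 errors. Further deposited files hold reads with several matches, with none, and of poor quality.

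Reads with the same start and strand were counted once per sample. The fragment length with the most plus and minus read pairs was 134 bp in sample 1 and 139 bp in sample 2, and reads were moved by 0.5 times its length. Windows of 200 bp in steps of 50 bp were tested with a one-sided exact Poisson test against the larger of the genome average (effective length 1.9e9 bp) and the surrounding 10 kb. A region needed a Benjamini-Hochberg adjusted p under 0.01, a fold of at least 5 and at least 20% of its reads on each strand, and windows within 200 bp were merged. These settings were fixed before the data were examined. On simulated data with added reads, 8 reads were recovered at 78% of sites in each sample, and 12 reads at 98% in sample 1 and 96% in sample 2. The added reads lay close around each site at a fixed fragment length, so these shares do not give the recovery of real sites. In reads moved at random within their own 10 kb, 0 regions were called. Such moves remove any clustering over shorter distances, so this is not a rate of false calls for the real reads.

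The plan counted a region as shared when calls overlapped by 1 bp. The samples are in different builds and coordinates were not converted, so this could not be applied as written. Instead, anchors every 500 kb were searched for the offset at which most read ends of both samples coincided, and 2519 of 5170 anchors were accepted with at least 12 coincident ends and 2 times the next best offset. Each region took the offset, among those of anchors within 10 Mb, with at least 4 coincident ends within 50 kb, an exact Poisson p of at most 1e-04 and 1.5 times the next best. This was devised after the data had been seen. A first version, which asked for 10 coincident ends per region, placed 46.7% of the sample 1 regions. The criteria were then changed because few regions were placed, which raised this to 84.6%. On simulated positions 94.4% were placed, all of them correctly. The simulation split the sample 1 reads of chromosome 10 and moved 1 part by fixed offsets. More ends were in common there than between the samples. It therefore does not give the accuracy between the samples, where pairing failed at the start of chromosome 9. Offsets were used only to pair regions, and each region is given in its own build.

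Other parts also departed from the plan. The planned motif test compared shares of regions, but reads cover few flank bases, so sites per covered position were tested with Fisher's exact test, and sequences were built from the sample 2 reads. This was decided after coverage had been seen, and motifs had been looked at before. On 50 simulated sets the motif test, adjusted over 10 motifs, made 0 false calls. Simulated centres and flanks were independent random bases of the same GC content, whereas the real ones had 52.3% and 50.0%. The 0 is therefore not a rate of false calls for the real sequences. A GATA site added to 60 regions was called in 33 sets by Fisher's exact test without adjustment, so this does not give the power of the adjusted test. Lanes used the fragment length of sample 1, chosen after lane 7 alone had given 95 bp. High background was first defined with the region included, which removed strong regions, and was then redefined without the 1 kb each side of the summit. Strand distance was the median minus end less the median plus end within 300 bp of the summit, added after the picture of the region with the most reads had been seen. Location classes, gene lists, placement on genes and the parts of the naming rule that need genes were not run, since no genome or annotation of mm8 or mm9 was used here. Calling on pooled reads was not run because of the builds.

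Regions were named by a rule fixed before the data were examined, the 15 shared regions with the most distinct reads and the 3 unpaired regions with the most reads per sample. Counts per region cover 400 bp around the summit. Shares have exact Clopper-Pearson 95% intervals and counts exact Poisson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Random placement used 1000 draws. Alternatives covered duplicates, thresholds, fold, background length, window, mismatches, depth, shift, overlap, lanes, motif background and pairing. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.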

Results

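Scl, also called Tal1, is a basic helix-loop-helix transcription factor of blood stem and progenitor cells that binds DNA at E-box sequences together with a class I partner. HPC-7 is a mouse haematopoietic progenitor line that grows in stem cell factor. Chromatin bound by Scl in HPC-7 cells was immunoprecipitated once, and the DNA was divided into 3 portions for sequencing. Portions 1 and 2 were read in lanes 7 and 8 at a single site and are treated here as sample 1. The remaining portion was read at another site and is sample 2. No untreated or control library was used here, so enrichment was measured against the reads around each window. Because every portion came from the same immunoprecipitation, agreement between the samples is technical, and all intervals and p-values below cover counting error only.

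Sample 1 held 5938819 aligned reads of 45 bp, of which 5632832 (94.8%) had a distinct start and strand. Lane 7 gave 1683055 of these reads and lane 8 gave 4255764, a ratio of 2.53 where the labels state a DNA ratio of 2. Sample 2 held 4296527 uniquely placed reads, of which 4151142 (96.6%) were distinct, and 86.1% of them were 32 bp long. The distinct reads amounted to 2.96 per kb in sample 1 and 2.18 per kb in sample 2, so an average window of 200 bp held 0.593 and 0.437 reads. Positions of sample 1 are in build mm9 and those of sample 2 in build mm8.

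The first question was where in the genome Scl chromatin was enriched. In sample 1, 1623 regions passed the threshold, with a median of 10 reads in the best 200 bp and a median enrichment of 12.7-fold. In sample 2, 834 regions passed, with a median of 11 reads and a median enrichment of 16-fold. The regions were narrow, with a median width of 250 bp in sample 1 and 300 bp in sample 2. They held 0.503% of the distinct reads of sample 1 (exact binomial 95% interval 0.497 to 0.509) and 0.408% of those of sample 2 (0.402 to 0.414). The number of regions had not levelled off with depth, since 75% of the reads gave 1060 regions in sample 1 and 517 in sample 2. Chromosomes 1, 8 and 17 held the most sample 1 regions, 213, 180 and 123, with 91 on chromosome 2 next. In sample 2 they held 76, 83 and 51, against 54 on chromosome 2. Read density was also high on chromosomes 1, 8 and 17 after a fit on GC content. How far that raised their numbers of regions was not tested.

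The second question was whether sequencing at the other site gave the same regions. Because the builds differ, regions were paired by the local offset at which the read ends of both samples coincided. This procedure was devised after the data had been seen and its criteria were loosened once. It placed 1373 of the 1623 regions of sample 1 (84.6%) and 684 of the 834 regions of sample 2 (82.0%). Of the placed regions, 409 of sample 1 (29.8%, exact binomial 95% interval 27.4 to 32.3) overlapped a region of sample 2, and 408 of sample 2 (59.6%, 55.9 to 63.4) overlapped a region of sample 1. The first, stricter version placed 758 regions of sample 1 and paired 228. In 1000 random placements of the sample 2 regions on their chromosomes, a mean of 0.275 and at most 3 overlapped (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). The pairing uses read ends found in both samples, and both samples come from the same immunoprecipitation, so these counts are not independent evidence of binding.

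The shared region with the most reads lay on chromosome 9, but its reads did not have the layout of fragments around a bound site. It spanned 35112651 to 35113250 in mm9 and 35054701 to 35055350 in mm8. Sample 1 had 330 distinct reads in the 400 bp around its summit (exact Poisson 95% interval 295 to 368) and sample 2 had 254 (224 to 287). Lane 7 alone held 232 distinct reads there and lane 8 alone 313, so most lane 7 positions recurred in lane 8. Each start and strand counts once, which sets an upper limit in a narrow span. The Poisson intervals do not allow for this limit. Enrichment over the surrounding 10 kb was 30.7-fold in sample 1 and 29.5-fold in sample 2, with adjusted exact Poisson p-values of 1.02e-222 and 6.98e-183. Plus-strand and minus-strand ends filled the same span, with a median distance from plus to minus ends of -8.0 bp in sample 1 and 23.0 bp in sample 2. The 10 kb background includes the region itself, and a 50 kb background raised the mean of both samples from 30.1-fold to 109-fold.

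**Figure D1:**
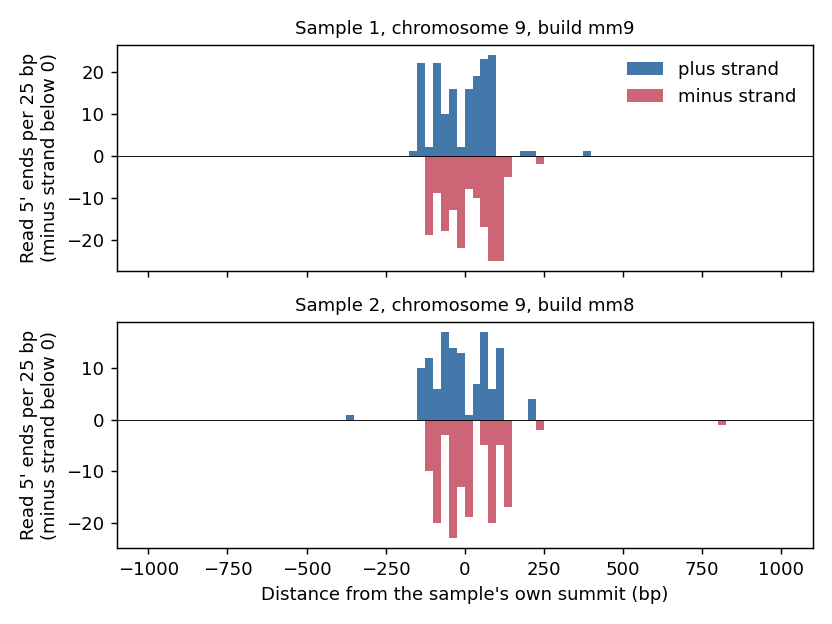
Read 5' ends per 25 bp around the shared region with the most reads on chromosome 9, plus strand above 0 and minus strand below, for sample 1 (mm9) and sample 2 (mm8), each centred on its own summit. Ends of both strands fill the same span with sharp borders, and the samples have 330 and 254 distinct reads in the central 400 bp.

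Among the 15 shared regions with the most reads, 6 had plus and minus ends apart by at least 0.5 fragment lengths in both samples. On chromosome 15 a region at 74916651 to 74917550 in mm9, and 74913551 to 74914350 in mm8, had 210 and 167 reads, an enrichment of 16.2-fold and 17.3-fold, and strand distances of 138 and 142.5 bp. On chromosome 8 the region at 87225351 to 87225800 in mm9, and 87591551 to 87592000 in mm8, was enriched 22.7-fold and 22.9-fold with distances of 127.5 bp in each sample. Regions on the same chromosome at 122895601 to 122896100 and 122893851 to 122894300 in mm9, and 123257701 to 123258150 and 123255901 to 123256350 in mm8, had enrichments of 14.9-fold and 17.3-fold, and 13.03-fold and 12.1-fold. The remaining ones lay on chromosome 11 at 3093001 to 3093350 in both builds, and on chromosome 18 at 3005151 to 3005950 in mm9 and 3005101 to 3005950 in mm8. Their enrichments were 7.69-fold and 5.95-fold, and 8.41-fold and 7.53-fold. With a 50 kb background the means of both samples at these 6 regions were higher and in another order: 73.6-fold on chromosome 15, 51.2-fold, 36.3-fold and 28.1-fold for those on chromosome 8 as listed, 11.96-fold on chromosome 11 and 36.5-fold on chromosome 18.

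Other regions with many reads had a short strand distance, and 8 of the 15 were below 0.5 fragment lengths in both samples. On chromosome 11 the region at 108872851 to 108873500 in mm9, and 108827601 to 108828300 in mm8, had 205 and 111 reads, 24.4-fold and 26.3-fold, with distances of 7.5 and 5.0 bp. The region on chromosome 4 at 70038951 to 70039450 in mm9, and 69864301 to 69864800 in mm8, reached 40.5-fold and 34.7-fold with distances of 31 and 20 bp. A region on chromosome 1 lay at 197067651 to 197068150 in mm9, and 196942151 to 196942800 in mm8, with 75 and 88 reads. It was enriched 32.9-fold and 27.5-fold with distances of 34.5 and 25 bp. On chromosome 18 the region at 40467651 to 40468150 in mm9, and 40433951 to 40434450 in mm8, was enriched 35.2-fold and 37.3-fold and was low in sample 1 only (61.0 bp, against 94.0 bp in sample 2). With a 50 kb background the means at these 4 regions rose to 81.9-fold, 125-fold, 82.6-fold and 127.5-fold, in the order given. The other 394 shared regions had median distances of 127.75 and 129 bp, and 17.8% of them were below 0.5 fragment lengths in both samples. Strand distances were measured after the picture of the chromosome 9 region had been seen. Genes near these regions were not analysed here, since no annotation of either build was used.

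In 9 of the 15 regions the surrounding 10 kb, without the 1 kb each side of the summit, held over 3 times the genome average of reads in at least 1 sample. These included all 6 regions with plus and minus ends apart in both samples, and 2 regions on chromosome 2 with enrichments of 4.52-fold to 5.30-fold on backgrounds of 24.5 to 26.0 reads per 200 bp. With a 50 kb background the means of both samples at these 2 regions rose from 4.76-fold to 23.2-fold and from 5.25-fold to 25.5-fold, and with all reads counted the latter fell to 1.26-fold. Without all regions of high background 369 shared regions were left, and without those of short strand distance in either sample 288 were left.

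Each sample also had regions that were not paired with a call in the other, 964 in sample 1 and 276 in sample 2. The 3 with the most reads in sample 2 lay on chromosome 9, at 2999901 to 3000400, 3026551 to 3026750 and 3025401 to 3025600 in mm8, with 172, 91 and 84 reads. Those of sample 1 lay on chromosome 2 at 98502801 to 98503150 and on chromosome 9 at 2999901 to 3000400 and 3025401 to 3025650 in mm9, with 241, 134 and 99 reads. These do not show binding in only 1 sample. When an offset of 0 was also allowed, 3 of the 3 regions of sample 2 and 2 of the 3 regions of sample 1 were paired, so their failure to pair came from the pairing at the start of chromosome 9. Over all unpaired regions that change paired 4 in each sample. The chromosome 2 region was another case, with 202 reads in sample 2 at 4.66-fold, under the 5-fold needed for a call. Its background in sample 2 was 26.0 reads per 200 bp.

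Read numbers were then compared across the 1649 placed regions called in either sample. Pearson's r of log2(count + 1) was 0.46 (bootstrap 95% interval 0.39 to 0.52) and Spearman's rho was 0.46. These are correlations across regions, which are not replicates. In the 409 shared regions r was 0.81. After the number of read ends that coincide between the samples was subtracted from each count, r was 0.31 over the 1649 regions. Those ends were counted over a wider span than the reads, and values below 0 were set to 0, so too many can be subtracted. At a region on chromosome 2, 294 ends were subtracted from 229 reads of sample 1 and 221 of sample 2. Exact binomial tests of the split of reads between the samples, against the split over all regions, had an adjusted p under 0.05 in 17 shared regions. All had more reads in sample 2 relative to that split, and 4 were among the 15 shared regions with the most reads. The binomial tests do not allow for the upper limit that counting each start and strand once sets in narrow, dense regions. Among regions called in sample 1 only, 4 passed with more reads in sample 1 and 2 with more in sample 2. Among those called in sample 2 only, 19 passed, all with more reads in sample 2. Calling in 1 sample only favours more reads in that sample, so these directions follow in part from the selection. The reference split, 59.3% from sample 1 against 57.6% of all distinct reads, was taken from these same regions. The passing regions include the 3 named regions of sample 2 and the 2 named regions of sample 1 at the start of chromosome 9, where the pairing failed. At regions called in sample 1 only, the median enrichment in sample 2 was 4.58-fold, and 83.2% of them reached at least 2-fold there, against 34.8% of 2459 background positions with a median of 1-fold. These folds rest on few reads, with a median of 4 sample 2 reads in 400 bp. Since an average 200 bp window of sample 2 held 0.437 reads, 1 read could already exceed 2-fold.

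**Figure D2:**
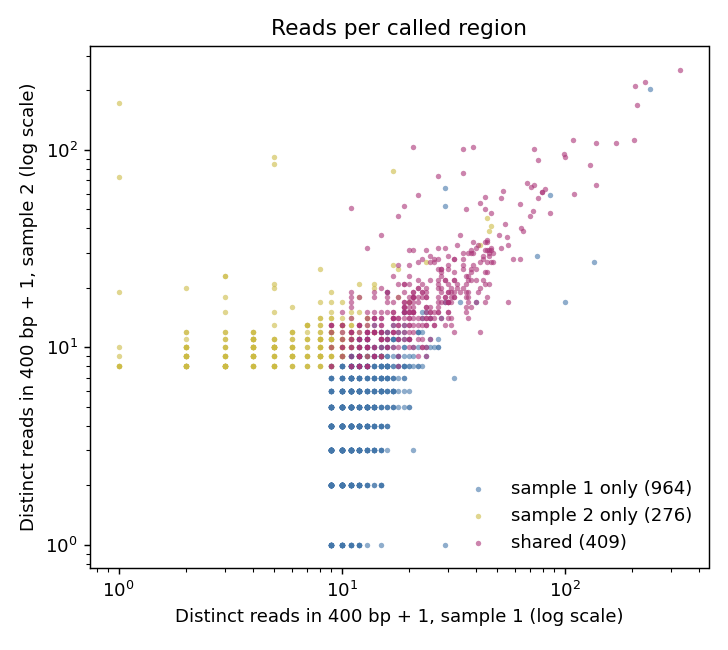
Distinct reads in 400 bp plus 1 in sample 1 (x axis) and sample 2 (y axis), both on log scales, for 409 shared regions, 964 regions called in sample 1 only and 276 called in sample 2 only. Shared regions rise together with r of 0.81. Medians are 21 and 16 reads in shared regions, 10 and 4 in regions called in sample 1 only, and 5 and 9 in those called in sample 2 only, with a few of the latter kinds at high counts.

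Lane 7 alone gave 240 regions and lane 8 alone gave 937. Of the lane 7 regions, 198 (82.5%, exact binomial 95% interval 77.1 to 87.1) overlapped a lane 8 region, and 197 of the lane 8 regions (21%, 18.5 to 23.8) overlapped a lane 7 region. Lane 8 thinned to the number of distinct reads of lane 7 gave 217 regions. Across the 1623 regions of sample 1, Pearson's r between the lanes was 0.63 and Spearman's rho 0.38. Exact binomial tests of the split between lanes had an adjusted p under 0.05 in 2 regions, and 42 had an unadjusted p under 0.05. Without read ends found in both lanes, 129 of 154 lane 7 regions overlapped.

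The last question was which sequence motifs lay under the shared regions. GATA motifs stood out. WGATAR, the site of GATA factors, was found in 225 of 409 regions (55.0%, exact binomial 95% interval 50 to 59.9) within 100 bp of the summit. Per kb of sequence covered by reads it occurred 5.39 times in the centres and 1.38 times in the flanks 400 to 600 bp away, a ratio of 3.90 (two-sided Fisher's exact test, adjusted p = 6.98e-12 over 10 motifs). The general E-box CANNTG was far less specific, with 7.29 sites per kb in the centres and 5.61 in the flanks (ratio 1.30, Fisher's exact test, adjusted p = 0.0419). Against reads of the same GC content its ratio was 1.10 and did not pass. Among E-boxes, CAGCTG was the most enriched, at 1.67 sites per kb against 0.277 (ratio 6.04, Fisher's exact test, adjusted p = 2.50e-05), although the flanks held only 4 such sites. Against reads of the same GC content the CAGCTG ratio was 2.16.

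Of the 431 E-boxes in the centres, 99 (23.0%) were CAGCTG, against 11.7% of 7138 E-boxes in reads of the same GC content (Fisher's exact test, adjusted p = 2.18e-09 over 10 E-boxes). CACCTG and CACATG made up lower shares, 10.9% against 18.3% and 14.2% against 19.7% (adjusted p = 0.000277 and 0.0155 by the exact test), although the rise of CAGCTG lowers the shares of all other E-boxes. Motifs of other blood transcription factor families were enriched as well. MGGAAR, the core of ETS factor sites, occurred 6.32 times per kb against 3.39 in the flanks (ratio 1.86, Fisher's exact test, adjusted p = 3.24e-05). TGYGGT, the core of RUNX sites, occurred 2.43 times per kb against 1.45 (ratio 1.67, adjusted p = 0.0398, exact test), but it did not pass under several alternatives. TGASTCA, CATMTG and CACCC had adjusted p-values of 1.0, 0.256 and 0.965 by the same exact test, the first on 5 flank sites. Each passed in at least 1 alternative: against reads of the same GC content TGASTCA was at 1.78-fold (adjusted p = 0.0198, exact test) and CACCC at 0.854-fold, and CATMTG was at 1.88-fold within 50 bp of the summit. Only 10.4% of flank bases were covered by reads, against 77.6% of centre bases, which limits the flank estimates.

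**Figure D3:**
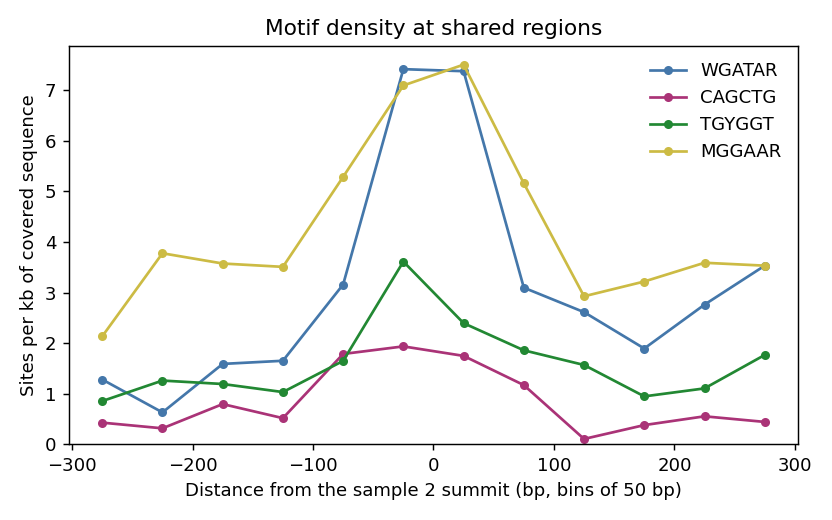
Sites per kb of covered sequence in bins of 50 bp (y axis) by distance from the sample 2 summit (x axis) at 409 shared regions, for GATA (WGATAR), E-box (CAGCTG), RUNX (TGYGGT) and ETS (MGGAAR) motifs. WGATAR reaches 7.42 and 7.38 sites per kb in the bins either side of the summit and 1.28 and 3.53 in the leftmost and rightmost bins.

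The composite of an E-box followed by a GATA motif after 7 to 9 bp, the arrangement described for Scl complexes, was found in 34 of the 409 regions (8.31%, exact binomial 95% interval 5.83 to 11.4). The flanks held 0 such sites in 8086 readable positions, so the enrichment was at least 1.92-fold against the 3 sites that a count of 0 allows (Fisher's exact test, adjusted p = 0.0231). Against reads of the same GC content the composite was 33.2 times as frequent (12 sites in 559118 positions). Without regions of short strand distance the centres still held 33 of the sites, but with fewer flank positions the floor was 1.497-fold and did not pass. Without regions of high background the floor was 1.29-fold and did not pass (adjusted p = 0.0608, exact test). WGATAR stayed at 4.56-fold without regions of short strand distance and passed. Counted by spacing, 21 pairs were 8 bp apart, 10 were 7 bp apart and 3 were 9 bp apart, while the spacings of 0 to 20 bp outside that range held 36 pairs in all. Per readable position, pairs at 7 to 9 bp were 5.45 times as frequent as at the other spacings (two-sided exact binomial p = 2.36e-11).

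**Figure D4:**
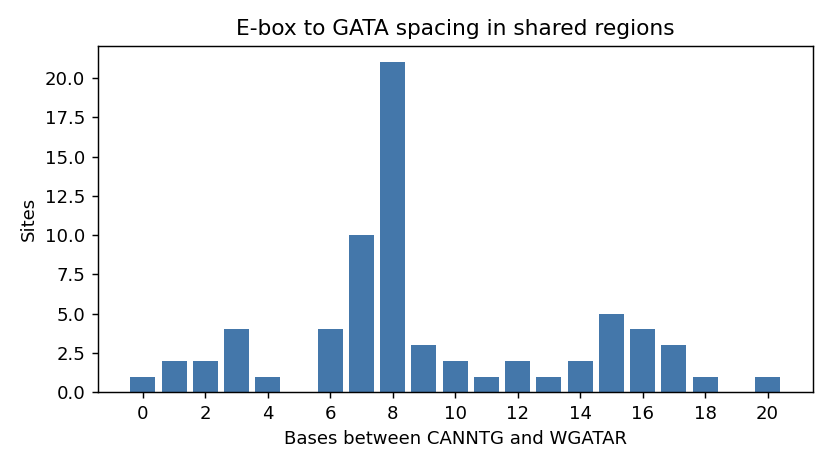
Number of E-box and GATA pairs in the centres of 409 shared regions (y axis) by the number of bases between CANNTG and WGATAR (x axis). The 21 pairs at 8 bp and 10 pairs at 7 bp exceed every other spacing from 0 to 20 bp.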

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

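All tests in this part were chosen after the results were seen, except those on depth and on windows near the threshold. Reads of sample 2 outside the main measurement carried signals above the limit that a count of 0 allows. Among reads with no genome match, 5.59% (69425 of 1242891, exact binomial 95% interval 5.55 to 5.63) held a sequencing adapter sequence, against 0.00189% of uniquely placed reads. Among reads with several matches, 0.244% (2721 of 1113231, 0.235 to 0.254) held the telomere repeat, against 0.00531% of uniquely placed reads.

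Read ends coincided between the samples far more often than at neighbouring offsets. In 1767 segments whose reads had not been used to accept an anchor, 53618 ends coincided at the placed offset and at most 3001 at offsets 10 to 60 bp away, which argues against chance. Copies of the same amplified fragments in every portion are a candidate explanation: per pair of reads the excess between sites was 0.853 of that between lanes (bootstrap 95% interval 0.839 to 0.867), above the bound of 0.8 set for it. Preferred break points common to separate libraries cannot be told apart from this, because the same ratio also lies below 1 by more than its interval, and the share of coincident ends inside regions was 2.057 times that outside (1.42 to 2.88). No biological explanation was tested.

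At the shared region with the most reads, ends of both strands filled the same span. A candidate explanation that was not decided is reads of short segments held in more copies than in the builds, in place of fragments around a bound site. Of the 14 other named shared regions, 7 had a strand distance below 0.5 fragment lengths in both samples, between the bounds of 2 and 8 set for it, and 8 was reached only with the region that prompted the test. Over all 409 shared regions the median distance in sample 1 was 126.5 bp. Region calling moved the ends of the strands toward each other by 0.5 fragment lengths, which favours regions with such a distance. This median therefore cannot decide the explanation for the other shared regions. No biological explanation was tested.

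More regions were called in sample 1 than in sample 2. Lower depth of sample 2 is a candidate explanation, since sample 1 thinned to the same number of distinct reads gave 1007 regions against 834. For the regions called in sample 1 only as a set, windows that passed by chance are argued against. There the median fold of sample 2 was 3.333 after subtracting the number of read ends found in both samples (bootstrap 95% interval 3.09 to 3.70). Those ends were counted over a wider span than the reads, so too many can be subtracted, which lowers the fold. The median at background positions, with shared ends kept, was 1. The value was above the bound of 2, but an average 200 bp window of sample 2 held 0.437 reads. A count of 1 read could thus exceed that bound, so how many of these regions passed by chance cannot be told. The test of the fold with shared ends kept gave 4.58, and the shared ends were subtracted only after that value was seen.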

How the results depend on the processing

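Calling on pooled reads, location classes, gene lists and placement on genes were not run. No paired analysis was possible because there is only 1 group. The alternatives on pairing, high background, strand distance, shared read ends, lane fragment length and the added motif backgrounds were chosen after seeing the data. Where a value moved, the cause was not tested, except that fewer reads were used in thinned, single-lane and mismatch-free settings.

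The number of shared regions (409) stayed within 1.5 times except for 249 with reads without mismatch, 172 with lane 7 in place of sample 1 and 228 with the first version of the pairing. Calls in a single sample, leaving out either one, gave 834 to 1623. Sample 1 regions (1623) became 3036 with all reads counted, 922 at an adjusted p under 0.001, 3499 under 0.05, 1002 without mismatch and 1007 with the same number of distinct reads as sample 2. Sample 2 regions (834) became 391 without mismatch. The share of sample 2 regions that overlapped (59.6%) was 48.4% with all reads, 72.0% under 0.001, 52.7% under 0.05, 53.7% with a 50 kb background, 63.5% with 400 bp windows, 72.8% without mismatch and 52.9% with the same number of distinct reads. That of sample 1 regions (29.8%) was 17.5% with all reads, 43.6% under 0.001, 16.2% under 0.05, 32.8% with a fold of 10, 27.0% with a 50 kb background and 43.5% with the same number of distinct reads. The correlation between samples (0.46) was 0.808 in shared regions and 0.517 with all reads. It was 0.312 after coincident ends were subtracted, which can subtract too many. Lane 7 regions overlapping lane 8 (198 of 240) fell to 129 without shared ends, out of 154 lane 7 regions then called.

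WGATAR, CAGMTG, CAGCTG and MGGAAR kept their direction and passed under every alternative run. CAGMTG is not separate from CAGCTG, since 99 of its 173 sites in the centres were CAGCTG. The other 74 were CAGATG on either strand, which CATMTG counts as well. CAGATG made up 17.2% of E-boxes in the centres against 14.3% in reads of the same GC content (Fisher's exact test, adjusted p = 0.201). CANNTG did not pass against shuffled centres (1.10), other reads (1.10), reads matched on GC (1.10) at an adjusted p under 0.001 (1.31) or without regions of short strand distance (1.22). TGYGGT did not pass at 0.001 (1.72), without high background (1.67) or without short strand distance (1.78). In calls of a single sample its ratios were 1.19 to 1.71, and it did not pass in those of sample 2 (1.19, adjusted p = 0.403 by Fisher's exact test). The composite did not pass without high background (at least 1.29) or without short strand distance (at least 1.497), where the flanks held 0 sites in fewer positions. It passed within 50 bp (at least 3.01), against shuffled centres (18.9), other reads (23.2) and reads matched on GC (33.2), and at 0.001 (at least 1.72). In calls of a single sample it passed at 6.04 in sample 1 and 8.16 in sample 2, on only 2 and 1 flank sites. CATMTG passed within 50 bp (1.88), against shuffled centres (1.41) and in calls of a single sample (1.42 to 1.73). TGASTCA passed against other reads (1.82) and reads matched on GC (1.78), and CACCC was lower than in reads matched on GC (0.854). Of 60 alternative folds at the 15 named regions, 30 only leave out 1 sample and so stay within the spread by construction. Of the other 30, from all reads or a 50 kb background, 6 stayed within the spread of the samples, 24 moved beyond it and 0 reversed.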

Other observations

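The tests on GC content, chromosome parts and CpG-rich regions were chosen after the results were seen, while those on spacing and on read number were written before. The spacing of E-box and GATA motifs was tested as a hypothesis taken from the arrangement described for Scl complexes. Pairs at 7 to 9 bp were 5.455 times as frequent per readable position as other pairs, above the bound of 2, which is consistent with a preferred spacing in these regions. GC content of the regions is argued against as the source of the GATA motifs, since WGATAR was 4.108 times as frequent as in other reads of the same GC content.

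Regions with more reads did not differ detectably in GATA content. The ratio of WGATAR density between regions above the median and the rest was 1.077 (95% interval 0.863 to 1.34, two-sided Fisher's exact test, p = 0.535). In the 30 CpG-rich regions the ratio to the other 379 was 0.750 (0.454 to 1.24, Fisher's exact test, p = 0.307). Both intervals include ratios on either side of 1, so neither hypothesis was decided, although a p over 0.05 had been written as the sign against each.

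Read density differed between chromosomes in both samples. Relative to the autosomes, the median per 1 Mb was 1.59 and 1.54 on chromosome 17, 1.52 and 1.47 on chromosome 8, 1.34 and 1.31 on chromosome 11, 1.247 and 1.252 on chromosome 1, and 0.247 and 0.305 on chromosome X, in samples 1 and 2. The fit on GC used sample 2 alone, whose reads have sequences. GC content explained 0.622 of the variance between autosomal bins, and chromosome 11 lay at -0.04 after a fit on GC. GC content is argued against as the whole source, since after a fit on GC the largest median residual among chromosomes 8, 17 and X was 1.126 on the log2 scale, that of X being below 0. Chromosomes 1, 8 and 17 stayed 0.49, 0.52 and 0.47 above 0. A gain alike over the whole chromosome may account for this, but it was not decided: the 10 Mb parts ranged over 0.606 on chromosome 1, above the limit of 0.6 set for it, and over 0.43 and 0.41 on chromosomes 8 and 17.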
